A study of Chlorocebus sabaeus with 18 samples.

How the data were processed

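Total RNA of COS-7 cells was hybridised to 18 Affymetrix Clariom D Human arrays, 3 in each of 6 groups: control, CGG, TRA2A overexpression, TRA2A knockdown, CGG with TRA2A overexpression and CGG with TRA2A knockdown. The authors deposited log2 values at the level of transcript clusters (genes), made by SST-RMA, a signal space transformation followed by robust multi-array averaging of all arrays together, with RMA and the Transcriptome Analysis Console named in the labels without versions. A second deposited table holds log2 values per the file headers at the level of exon regions and exon-exon junctions, made with SST-RMA and a detection-above-background step. It lists a part of the transcript clusters, 43111 of 135750, and its gene-level values were checked to equal those of the first table. No raw intensities or detection calls were part of the tables, the depth of an array is not a count, and the number of arrays per group limits the precision. Probes on these arrays were designed for human transcripts, so a monkey transcript that differs from the human sequence can give a lower signal in all groups alike, and comparisons were made between groups for the same probes. Transfected sequence is present in only some groups, so its signal need not be alike between them. Groups were read from the array titles, which carry the group and a replicate number from 1 to 3, and no array was left out. Same-numbered arrays of different groups were tested for likeness, and the labels name no pairing.

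Comparisons were made in R 4.3.3 with limma 3.58.1 (lmFit and eBayes) and the data.table package (version 1.17.8), with 1 model of the 6 group means over all 18 arrays and no covariate. Transcript clusters with a mean log2 value above the median of such means (4.14) were tested, 67854 of 135750, of which 25413 carry 1 gene symbol, 874 several and 41567 none. There were 5 pairwise comparisons (CGG, TRA2A overexpression and TRA2A knockdown against control, and CGG with overexpression or knockdown against CGG) and 2 interactions (the CGG change with altered TRA2A minus the CGG change without). A call was an adjusted p under 0.05 by the Benjamini-Hochberg method over all tested transcript clusters in limma's moderated test, two-sided. At the exon level the value of a feature minus the value of its gene in the same array was tested in the same model for the 5 pairwise comparisons. This covered 230888 features (135465 exon regions and 95423 junctions) with a mean above the median of exon-level means (7.46), in 18009 genes that passed the gene-level filter and had at least 3 features. The p-values measure the spread between arrays.

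The 28 gene lists covered splicing factors, proteins linked to CGG repeat RNA, stress, interferon, inflammatory, p53, cell-cycle, metabolic, ribosomal, signalling, matrix and cytoskeletal genes, and markers of other cells. Each of the 27 lists with at least 5 measured genes was tested with limma's camera at the preset correlation of 0.01, with the p adjusted over the lists. The test was run again with an estimated correlation and with fry, which asks whether the genes of a list move one way and does not compare the list with other genes. List members were counted as called over all tested transcript clusters and when adjusted over the list alone. Pearson and Spearman correlations of log2 fold changes across 23836 named genes were computed for 4 pairs of comparisons that share no array, with a jackknife error over arrays. The comparisons, lists and tests given above and the genes to be named were chosen before the data were examined. Tests, lists and reference groups chosen later are named as such where they are given. The genes named were TRA2A, TRA2B and FMR1 in every comparison. Added to these were, among called genes whose arrays of the groups compared do not overlap, the 10 largest rises and 10 largest falls, or, where none was called, the 3 with the smallest p, and from each list up to 4 called members with the largest change, otherwise at most 2 with the smallest p as values. Interactions had no list members and no overlap condition. Only a single gene symbol counted, without systematic names of clones, uncharacterised loci, microRNAs and small nuclear or nucleolar RNAs, and a gene with several transcript clusters was read from the one with the highest mean. At the exon level the 5 features per direction with the largest change in genes with such symbols were named, those of TRA2A in part only as a range. The features of the genes TRA2A and CHP1 beyond these and the features in the plot of CGG-dependent probes were chosen after their values were seen.

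Alternatives were no filter, a filter at the 75th percentile (5.12, 33934 transcript clusters), quantile normalization, the variance from only the arrays compared, and a trended and robust variance. Further ones were the replicate number as a block, rehybridisation as a covariate, a 2-fold change with an unadjusted p under 0.05, exon values relative to the median of the exons of the gene, and leaving out each array in turn. Other splits of the arrays into groups of the same sizes were fitted in the same way. Detection was tested on simulated data in groups of 3 arrays. In the same data 100 features were changed by 1 log2 unit and 100 by 2, among unchanged ones. The CGG comparison then recovered 43 of 100 changes of 1 log2 unit and 94 of 100 changes of 2 at gene level with 8 false calls, the interaction 12 and 79 with 6, and the exon level 10 and 65 with 4. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9 and pandas 2.3.3.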

Results

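Gene expression was measured in COS-7 cells, a kidney cell line of the green monkey Chlorocebus sabaeus, with 18 Clariom D Human arrays, which carry probes designed against human transcripts. The arrays fell into 6 groups of 3: controls, cells transfected with the FMR1 5' untranslated region holding 60 CGG repeats (CGG), cells overexpressing TRA2A, cells with TRA2A knocked down, CGG cells with TRA2A overexpression, and CGG cells with TRA2A knockdown. Expansion of these repeats causes FXTAS, the fragile X-associated tremor/ataxia syndrome, and TRA2A is a splicing regulator of the Tra2 family. The labels mark CGG array 1 and TRA2A knockdown array 3 as rehybridised, and the titles name GFP for TRA2A overexpression without CGG and for no other group. They give no transfection for the controls, whose condition reads COS-7, COS-6 and COS-5 beside a cell line given as COS-7, and do not say whether the arrays of a group came from separate cultures. The gene-level values had medians of 4.14 to 4.20 on the log2 scale in the 18 arrays, pairs of arrays correlated at 0.976 to 0.989 across transcript clusters, and the number of arrays limits the precision. The leading principal component held 12.7% of the variance and placed the controls at -79.5, -63.6 and -30.7, and the other 15 arrays between -10.7 and 36.2.

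TRA2A (TC0700010472.hg.1) moved with its labels. Its mean log2 value was 14.62 ± 0.07 (SD, n = 3) in controls and 14.57 ± 0.12 in CGG cells. It was 18.53 ± 0.16 with overexpression and 17.16 ± 0.06 with overexpression in CGG cells. With knockdown it was 11.55 ± 0.44, and 11.82 ± 0.17 in CGG cells. The exon-level values of TRA2A did not rise alike with overexpression. A region went from a mean of 10.77 in controls to 19.33, and another from 12.89 to 12.21. The size of the gene-level rise therefore depends on the probes averaged. TRA2B (TC0300013428.hg.1), the paralog of TRA2A, had means between 16.43 and 16.79 in the 6 groups, and FMR1 (TC0X00008668.hg.1), the gene that carries the repeat, between 12.31 and 12.77. Neither passed the test in any of the 7 gene-level comparisons.

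**Figure D1:**
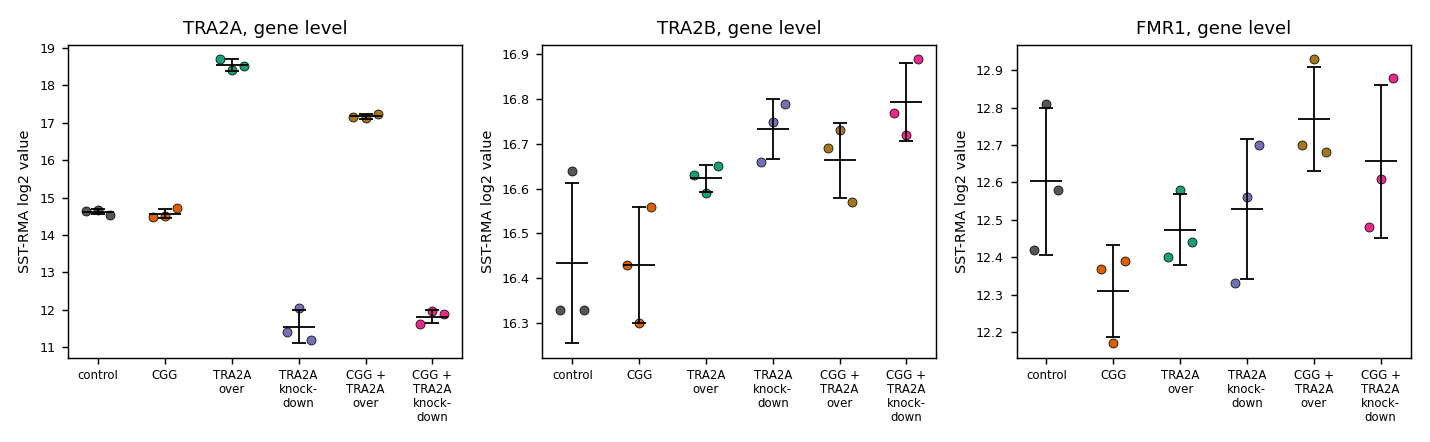
Gene-level log2 values of TRA2A, TRA2B and FMR1 in each of the 18 arrays by group, with the mean and SD of the 3 arrays of a group; each panel has its own axis range. TRA2A lies between 18.4 and 18.7 in the overexpressing arrays without CGG and below these in all 6 knockdown arrays.

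The comparison of CGG cells with controls asks which genes differ in cells with the repeat construct. No group holds the construct without the repeat, and the labels give no transfection for the controls. The repeat is therefore not separated from transfection or handling. Of the genes called here, 187 were called the same way in overexpressing and in knockdown cells against controls. HMOX1 (TC2200007204.hg.1), the heme oxygenase induced by oxidative stress, was 57.0-fold higher (log2 change 5.83 ± 0.28 SE, n = 3 and 3, adjusted p = 5.26e-10). SQSTM1, the autophagy receptor p62, was 14.8-fold higher (log2 change 3.89 ± 0.17), GDF15, a secreted stress cytokine, 14.1-fold (3.82 ± 0.25), and FABP3, a fatty acid-binding protein, 10.4-fold (3.37 ± 0.25). AKR1B15 (4.93 ± 0.17) and AKR1B10 (3.32 ± 0.26), aldo-keto reductases, rose with the pseudogene AKR1B10P1 (2.64 ± 0.26), whose near-identical sequences the probes may share. GPNMB, a glycoprotein of lysosomes and melanosomes (2.90 ± 0.22), ATP6V0B, a subunit of the vacuolar proton pump (2.67 ± 0.50), and CSF1, the macrophage growth factor (2.53 ± 0.19), completed the 10 largest rises. NPTX1 (TC1700011984.hg.1), neuronal pentraxin 1, was 11.9-fold lower (log2 change -3.57 ± 0.17, adjusted p = 5.26e-10). ALPK2, an alpha kinase (-2.21 ± 0.20), MALT1, the paracaspase of NF-kB signalling (-2.19 ± 0.23), ANKRD1, a muscle ankyrin repeat protein (-2.16 ± 0.23), and BMP4, a bone morphogenetic protein (-1.96 ± 0.23), followed. WWC1 (-1.85 ± 0.25), CYP24A1, the vitamin D 24-hydroxylase (-1.56 ± 0.21), MTMR10 (-1.56 ± 0.25), TAFA4 (-1.53 ± 0.17) and CD24 (-1.53 ± 0.20) also fell.

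In all, 454 of 67854 transcript clusters passed at an adjusted p under 0.05, 342 higher and 112 lower in CGG cells, and 212 and 71 of these differed at least 2-fold. The split by direction was 392 and 162 after quantile normalization, 233 and 192 without control array 2, and 345 and 305 by a fold of 2 with an unadjusted p under 0.05. Of all 67854 tested, 9750 had no overlap between the arrays of the groups, which chance gives for 10%. TRA2A differed by a log2 change of -0.05 ± 0.19 (adjusted p = 0.943) and FMR1 by -0.29 ± 0.17 (adjusted p = 0.499). The count was 196 without control array 1, 703 without control array 3, 288 without CGG array 2 and 179 without CGG array 3, and ATP6V0B lost its call without CGG array 2 or 3. With the variance estimated from the 6 arrays alone, 55 transcript clusters passed, and ATP6V0B, WWC1, MTMR10 and, of the list genes given next, BAG3, DUSP5, EGR1, IFI44, IRF1, IRF9, NFKBIA and THBS1 were not among them.

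Of the gene lists fixed beforehand, cholesterol synthesis and the unfolded protein and integrated stress response rose most in CGG cells. Of 26 measured stress-response genes 13 rose and 13 did not pass, and 23 rose when adjusted over the list alone, with a list median of 0.99. DDIT3, the stress-induced transcription factor CHOP, rose by 2.46 ± 0.24, SLC7A11, the cystine transporter, by 2.07 ± 0.21, and DNAJB9, a chaperone of the endoplasmic reticulum, by 1.69 ± 0.18. Of 20 cholesterol genes 12 rose, and 20 when adjusted over the list alone, with HMGCS1 (2.07 ± 0.22) and MSMO1 (1.55 ± 0.18), both enzymes of sterol synthesis, and INSIG1, the sterol-regulated brake of that pathway (1.76 ± 0.20), in front. Of 21 p53 targets 6 rose (7 when adjusted over the list alone), among them CDKN1A, the cell-cycle inhibitor p21 (2.05 ± 0.21). Of 30 interferon-response genes 3 rose (7 when adjusted over the list alone), IRF1, an interferon-induced transcription factor (1.25 ± 0.17), IFI44 and IRF9. IRF9 lost its call without CGG array 3, and IFI44 without control array 1 or 2 or CGG array 1 or 3. These 4 lists passed camera, a test of a list against all other genes, with both the preset and an estimated correlation, with adjusted p = 0.00037, 4.74e-05, 0.0415 and 0.0163 with an estimated correlation in the order given.

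The preset correlation called 11 of 27 tested lists in CGG cells, all higher, and 7 of them lost the call with an estimated correlation. Of 21 NF-kB targets 2 were higher and 1 lower, and 4 and 1 when adjusted over the list alone (adjusted p = 0.110 with an estimated correlation). SOD2, the mitochondrial superoxide dismutase, rose by 1.54 ± 0.17 and NFKBIA, the inhibitor of NF-kB, by 1.52 ± 0.21. Of 16 heat shock genes 2 rose, and 4 when adjusted over the list alone (adjusted p = 0.110 with an estimated correlation), with BAG3, a co-chaperone, at 1.47 ± 0.18. Of 31 hypoxia and glycolysis genes 3 rose, while 9 were higher and 2 lower when adjusted over the list alone (adjusted p = 0.148 with an estimated correlation). Of 24 immediate early genes 2 were higher and 1 lower, and 6 and 3 when adjusted over the list alone (adjusted p = 0.585 with an estimated correlation). EGR1, a transcription factor, was the one that fell (-1.50 ± 0.23), and DUSP5, a phosphatase of ERK, rose by 1.40 ± 0.23. No single gene passed in limma among 32 nuclear oxidative phosphorylation genes, 33 core spliceosome genes and 30 ribosomal proteins, where 8, 2 and 1 had an unadjusted p under 0.05. These lists had adjusted p = 0.380, 0.464 and 0.743 with an estimated correlation, and the last pair also lost the preset call after quantile normalization.

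No SR or hnRNP splicing protein passed in limma in CGG cells (0 of 23 and 0 of 22, with 4 and 2 at an unadjusted p under 0.05). Among markers of other cells 1 of 10 epithelial genes rose, CLDN4, a tight-junction claudin (2.16 ± 0.28). Of 8 leukocyte, 9 endothelial and 10 neuronal markers 0 passed, with 1, 3 and 2 at an unadjusted p under 0.05. Of 3 measured erythroid markers 0 passed in limma in CGG cells, with HBA1 at 0.98 ± 0.23 and HBA2 at 0.85 ± 0.20, and 2 were higher when adjusted over the list alone and 1 after quantile normalization. The erythroid median was 0.85 in CGG cells, and 0.65 with overexpression and 0.61 with knockdown, where 0 passed and 2 and 3 had an unadjusted p under 0.05. The matrix and TGF-beta list had 1 gene higher and 2 lower of 24, and 6 and 8 when adjusted over the list alone, with COL6A1, a collagen chain, at 1.13 (a call lost without any 1 of the arrays but CGG array 2), THBS1, thrombospondin 1, at -1.15 ± 0.18, and TIMP3, an inhibitor of matrix proteases, at -1.33. Of 23 proteins linked to CGG repeat RNA 1 was higher, LMNA, a call lost without control array 1 or 2 or CGG array 1 or 3. The lists for cell division, histones, mitochondrially encoded transcripts, metallothioneins, paraspeckles, stress granules and actin had no list call in CGG cells, but after quantile normalization mitosis (adjusted p = 0.00639) and the metallothioneins (adjusted p = 0.0332) were called lower. With an estimated correlation neither of these lists passed on the values as deposited. The median and the mean of a list had opposite signs for the hnRNP and stress granule lists with CGG, the immediate early and leukocyte lists with overexpression, and the paraspeckle list with knockdown. They did so for the SR, hnRNP and stress granule lists with knockdown in either background, for the p53, epithelial and neuronal lists with overexpression in CGG cells, and for the S phase, actin, leukocyte and epithelial lists with knockdown in CGG cells. None of these passed the list test.

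**Figure D2:**
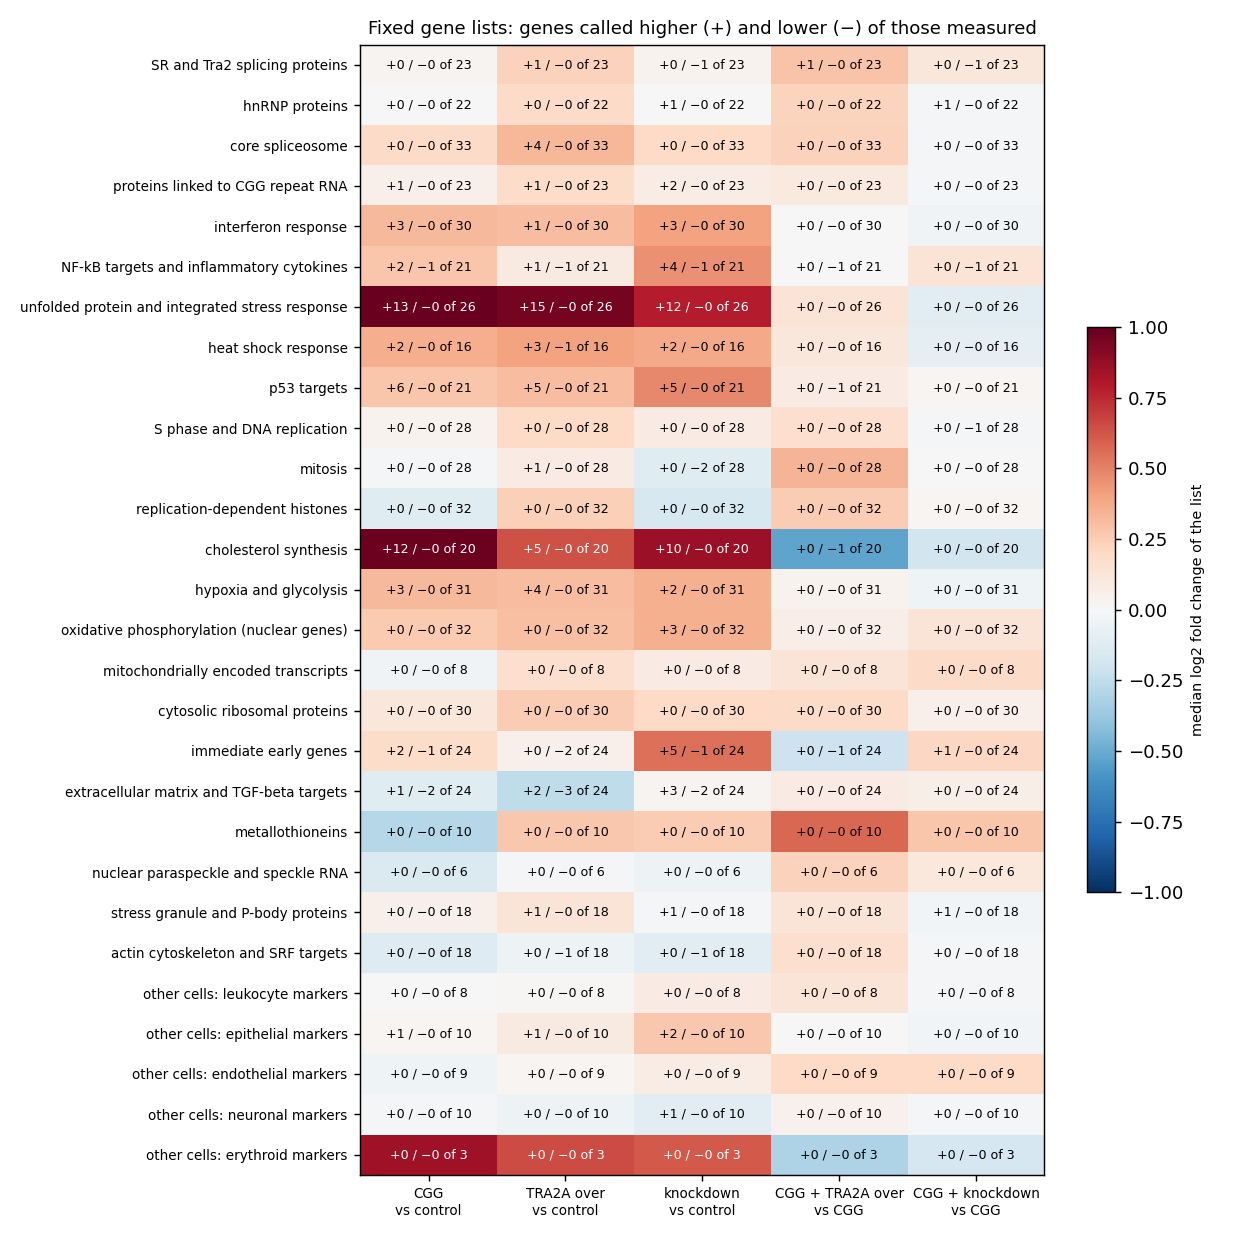
Median log2 fold change (colour) of each of the 28 fixed gene lists in the 5 pairwise comparisons, with the number of genes called higher and lower out of those measured. The stress-response and cholesterol lists have medians of 0.99 and 0.98 in CGG cells; the erythroid list has 3 measured genes and no list test.

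The comparison of TRA2A-overexpressing cells with controls asks which genes differ in cells with an excess of the splicing factor, and it does not separate TRA2A from the GFP named in their titles. As the labels give no transfection for the controls, it does not separate TRA2A from transfection either. TRA2A itself rose most after HMOX1 (log2 change 3.91 ± 0.19 SE, n = 3 and 3, adjusted p = 6.33e-10). HMOX1 was 55.1-fold higher (5.78 ± 0.28, adjusted p = 6.33e-10), SQSTM1 12.7-fold (3.67 ± 0.17) and AKR1B15 11.2-fold (3.48 ± 0.17). LCN2, the iron-siderophore-binding lipocalin 2 (2.63 ± 0.28), ATP6V0B (2.60 ± 0.50), DDIT3 (2.32 ± 0.24), AKR1B10 (2.20 ± 0.26), ARRDC3, an arrestin-domain protein (2.03 ± 0.35), and GPNMB followed. NPTX1 was 10.2-fold lower (-3.36 ± 0.17). Next came ITGB3, the integrin beta 3 chain (-2.06 ± 0.23), PSG5, a pregnancy-specific glycoprotein (-2.05 ± 0.20), CRYAB, a small heat shock protein (-1.96 ± 0.31), and ALPK2 (-1.94 ± 0.20). WWC1 (-1.83 ± 0.25), TM4SF1, a membrane protein of the tetraspanin-like family (-1.80 ± 0.16), TGM2, a transglutaminase (-1.76 ± 0.20), RNF145, a ubiquitin ligase of the endoplasmic reticulum (-1.68 ± 0.17), and MALT1 (-1.65 ± 0.23) also fell.

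In all, 846 transcript clusters passed, 644 higher and 202 lower, and 291 and 138 of these differed at least 2-fold. After quantile normalization 783 passed, 434 higher and 349 lower, 836 passed without control array 2, 454 higher and 382 lower, and a fold of 2 with an unadjusted p under 0.05 gave 433 higher and 424 lower. The count was 207 without control array 1, 1524 without control array 3, and 492, 188 and 188 without overexpression arrays 1, 2 and 3. It was 33 with the variance estimated from the 6 arrays alone and 563 without the filter on low values. ATP6V0B lost its call without control array 1 or overexpression array 2 or 3, ARRDC3 without control array 1, and these 2, CRYAB, MALT1 and the list genes BAG3, INSIG1, HERPUD1, IRF1, LMNA and TMEM97 with the variance of the 6 arrays alone.

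Among the fixed lists, 15 of 26 stress-response genes rose in overexpressing cells, and 22 when adjusted over the list alone (adjusted p = 0.00207 with an estimated correlation). HERPUD1, of the degradation of misfolded proteins, rose by 1.47 ± 0.23 beside DDIT3. Of 20 cholesterol genes 5 rose, and 14 when adjusted over the list alone (adjusted p = 0.00409 with an estimated correlation). TMEM97, a sterol-regulated membrane protein, rose by 1.61 ± 0.23 and INSIG1 by 1.21 ± 0.20. Of 30 interferon genes 1 rose, IRF1 at 1.24 ± 0.17, and 8 when adjusted over the list alone (adjusted p = 0.0195 with an estimated correlation).

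The preset correlation called 14 of 27 lists with overexpression, all higher, and the other 11 lost the call with an estimated correlation. Of 33 core spliceosome genes 4 rose, SNRPC, SF3A1, PRPF19 and PRPF4, and 7 when adjusted over the list alone (adjusted p = 0.111 with an estimated correlation). Each of these 4 calls ended without any 1 of the overexpression arrays and without control array 1 or 2. Of 23 SR and Tra2 proteins TRA2A was the 1 that passed, while 5 were higher and 1 lower when adjusted over the list alone (adjusted p = 0.111 with an estimated correlation). As this list holds TRA2A, the gene overexpressed, its preset call is partly given by the treatment, and it was not tested without TRA2A. Of 21 p53 targets 5 rose, and 7 when adjusted over the list alone (adjusted p = 0.111 with an estimated correlation), with TP53I3, an oxidoreductase, at 1.42 ± 0.19. Of 16 heat shock genes 3 were higher and 1 lower, and 9 and 1 when adjusted over the list alone (adjusted p = 0.139 with an estimated correlation), with BAG3 at 1.47 ± 0.18 against CRYAB. Of 31 hypoxia and glycolysis genes 4 rose, while 10 were higher and 1 lower when adjusted over the list alone (adjusted p = 0.139 with an estimated correlation). Of 23 proteins linked to CGG repeat RNA 1 rose, LMNA, lamin A (1.04 ± 0.17), and 4 when adjusted over the list alone (adjusted p = 0.265 with an estimated correlation).

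The hnRNP, S phase, histone, oxidative phosphorylation and ribosomal lists had no gene past the test in limma with overexpression, with 4, 6, 0, 12 and 10 genes at an unadjusted p under 0.05. They had adjusted p = 0.483, 0.465, 0.586, 0.265 and 0.426 with an estimated correlation. When adjusted over the list alone, 5 oxidative phosphorylation genes were higher, and 4 ribosomal genes higher and 1 lower. The hnRNP, S phase, histone and CGG-linked lists lost the preset call after quantile normalization, and the matrix and TGF-beta list, with 2 genes higher and 3 lower of 24, and 3 and 6 when adjusted over the list alone, was then called lower (adjusted p = 0.0140). With an estimated correlation the matrix list did not pass on the values as deposited. Of 10 epithelial markers 1 passed, ESRP1, a splicing regulator of epithelia, at 0.71 ± 0.17, and its call ended without any 1 of the arrays other than control array 3.

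The comparison of TRA2A-knockdown cells with controls asks which genes differ in cells with less TRA2A. The labels name no control siRNA and give no transfection for the controls, so a loss of TRA2A is not separated from transfection. TRA2A was 8.44-fold lower (log2 change -3.08 ± 0.19 SE, n = 3 and 3, adjusted p = 2.42e-08). HMOX1 was 53.3-fold higher (5.74 ± 0.28, adjusted p = 1.11e-09), and AKR1B15 (4.70 ± 0.17), GDF15 (3.82 ± 0.25), AKR1B10 (3.35 ± 0.26), SQSTM1 (3.28 ± 0.17), CSF1 (3.14 ± 0.19), ATP6V0B (3.10 ± 0.50), ARRDC3 (3.03 ± 0.35), GPNMB (2.93 ± 0.22) and SPP1, the secreted protein osteopontin (2.87 ± 0.22), rose. NPTX1 was 10.7-fold lower (-3.42 ± 0.17). The other large falls were BMP4 (-2.59 ± 0.23), ANKRD1 (-2.52 ± 0.23), ALPK2 (-2.26 ± 0.20), CHP1, a calcium-binding partner of sodium-proton exchangers (-2.16 ± 0.19), WWC1 (-2.14 ± 0.25), IGF2BP2, an mRNA-binding protein (-2.10 ± 0.18), TENM3, a teneurin adhesion protein (-2.01 ± 0.30), and GJA1, connexin 43 (-1.97 ± 0.24).

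In all, 1049 transcript clusters passed, 764 higher and 285 lower, and 368 and 163 of these differed at least 2-fold; after quantile normalization 1016 passed, 617 higher and 399 lower, and 890 passed without control array 2, 510 higher and 380 lower. The count was 512 without control array 1, 481 without knockdown array 1, 563 without knockdown array 3 and 526 without the 2 rehybridised arrays. It was 135 with the variance estimated from the 6 arrays alone, where ATP6V0B and the list genes CCN2, ESRP1, PTBP2 and TOP2A did not pass.

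In knockdown cells 12 of 26 stress-response genes rose, and 22 when adjusted over the list alone (adjusted p = 0.00239 with an estimated correlation), with DNAJB9 at 1.84 ± 0.18 and DDIT3 at 1.71 ± 0.24. Of 20 cholesterol genes 10 rose, and 19 when adjusted over the list alone (adjusted p = 0.000275 with an estimated correlation). INSIG1 rose by 2.77 ± 0.20, HMGCS1 by 2.12 ± 0.22 and IDI1, an isomerase of isoprenoid synthesis, by 1.72 ± 0.18. Of 21 NF-kB targets 4 were higher and 1 lower, and 11 and 1 when adjusted over the list alone (adjusted p = 0.0215 with an estimated correlation). NFKBIA rose by 1.86 ± 0.21 and CXCL8, the neutrophil chemokine interleukin 8, by 1.72 ± 0.31. Of 21 p53 targets 5 rose, and 10 when adjusted over the list alone (adjusted p = 0.0224 with an estimated correlation), with CDKN1A at 2.42 ± 0.21. Of 30 interferon genes 3 rose, and 8 when adjusted over the list alone (adjusted p = 0.00974 with an estimated correlation), with IRF1 at 1.57 ± 0.17 and IRF9 at 1.32 ± 0.21. Among hnRNP proteins PTBP2, the neuronal paralog of the splicing repressor PTBP1, rose by 1.38 ± 0.25. Among P-body proteins DCP2, the mRNA-decapping enzyme, rose by 1.77 ± 0.20.

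The preset correlation called 14 of 27 lists with knockdown, 12 higher and 2 lower, and 9 of them lost the call with an estimated correlation. Of 24 immediate early genes 5 were higher and 1 lower, and 13 and 1 when adjusted over the list alone (adjusted p = 0.113 with an estimated correlation). DUSP5 rose by 1.88 and CCN2, a matricellular protein, fell by 1.09. Of 32 oxidative phosphorylation genes 3 rose, and 10 when adjusted over the list alone, and of 16 heat shock genes 2 rose, and 5 when adjusted over the list alone. Of 31 hypoxia and glycolysis genes 2 rose, while 8 were higher and 1 lower when adjusted over the list alone. These 3 lists each had adjusted p = 0.113 with an estimated correlation. The core spliceosome and ribosomal lists had no gene past the test in limma (8 and 5 at an unadjusted p under 0.05). They had adjusted p = 0.360 and 0.481 with an estimated correlation and lost the preset call after quantile normalization. The mitosis list was lower, with 2 of 28 genes called and 5 when adjusted over the list alone (adjusted p = 0.356 with an estimated correlation), and TOP2A, topoisomerase II alpha, fell by 1.08. The histone list was lower with 0 of 32 genes called and 7 at an unadjusted p under 0.05 (adjusted p = 0.580 with an estimated correlation). Of 10 epithelial markers 2 rose, CLDN4 (2.55 ± 0.28) and ESRP1 (0.90 ± 0.17), with adjusted p = 0.175 with an estimated correlation, and ESRP1 did not pass without the 2 rehybridised arrays.

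The 3 comparisons with controls called many of the same genes. CGG and TRA2A-overexpressing cells shared 183 higher and 58 lower genes, where independent lists would share 3.25 and 0.333. CGG and knockdown cells shared 234 higher and 65 lower, where 3.85 and 0.470 would be shared, and the overexpressing and knockdown cells 268 and 63, where 7.25 and 0.848 would be. HMOX1, SQSTM1, GDF15, DDIT3 and HMGCS1 were higher, and NPTX1 lower, in all 3, where the HMGCS1 call with overexpression ended without overexpression array 3. The same control arrays stand in each comparison, which by itself gives fold changes a correlation near 0.5 in simulated data without any change. The correlations across the 67854 transcript clusters were 0.681, 0.684 and 0.659, and the covariances 0.0829, 0.0811 and 0.0817, against a highest simulated value of 0.0346. A part of the shared calls may still come from the shared controls. Against the mean of the other 2 treated groups, a reference chosen after the data were seen, 9 of 67854 transcript clusters passed in CGG cells, 126 in overexpressing cells and 238 in knockdown cells, and 5, 29 and 130 of them had passed against controls in the same direction.

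**Figure D3:**
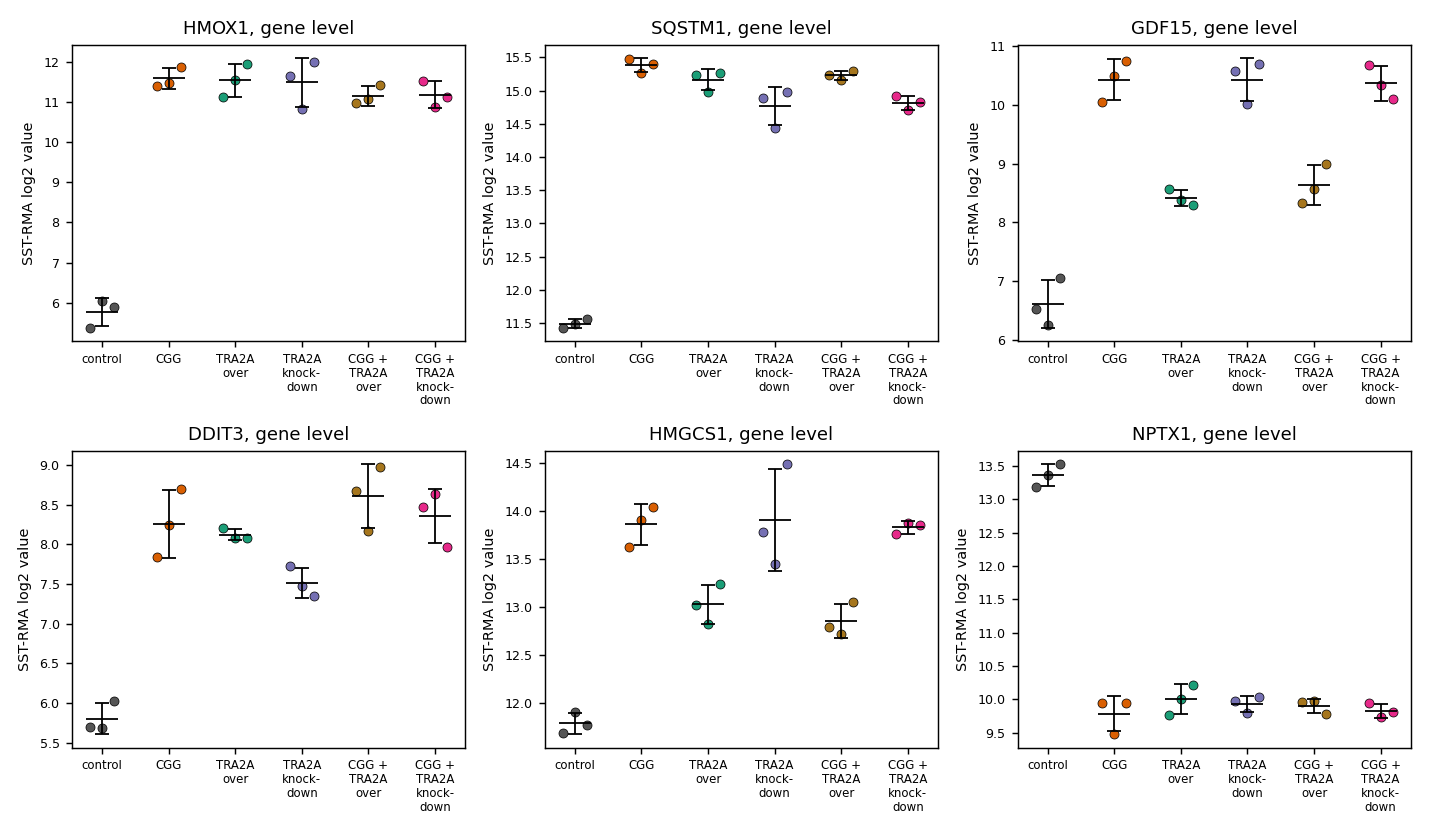
Gene-level log2 values of HMOX1, SQSTM1, GDF15, DDIT3, HMGCS1 and NPTX1 in each of the 18 arrays by group, with the mean and SD of the 3 arrays of a group; each panel has its own axis range. The 3 control arrays lie on one side of the 15 other arrays in each panel, for HMOX1 at a mean of 5.76 against 11.16 to 11.59.

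The comparison of CGG cells with and without TRA2A overexpression asks which genes differ with an excess of TRA2A beside the repeat. TRA2A was 6.03-fold higher (log2 change 2.59 ± 0.19 SE, n = 3 and 3, adjusted p = 2.78e-06). WIF1, a secreted inhibitor of Wnt signalling, was 3.65-fold higher (1.87 ± 0.24, adjusted p = 0.00312), and WNT4 (1.15 ± 0.20), ZNF234, a zinc finger protein (1.10 ± 0.19), and TAFA4 (0.95 ± 0.17) also rose. FABP3 was 6.48-fold lower (-2.70 ± 0.25, adjusted p = 7.65e-05) and GDF15 3.47-fold lower (-1.79 ± 0.25, adjusted p = 0.00810). TMEM154 (-1.60 ± 0.21), THRSP, a regulator of fatty acid synthesis (-1.50 ± 0.24), and TGM2 (-1.43 ± 0.20) fell, and so did AKR1B15 (-1.36 ± 0.17), ITGB3 (-1.34 ± 0.23), MAOA, monoamine oxidase A (-1.31 ± 0.21), ELOVL6, a fatty acid elongase (-1.28 ± 0.19), and SAT1, the acetyltransferase of polyamine breakdown (-1.23 ± 0.19).

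In all, 26 transcript clusters passed, 6 higher and 20 lower, and 6112 had an unadjusted p under 0.05. The count was 14, 14 and 8 without CGG arrays 1, 2 and 3, and 8, 5 and 166 without arrays 1, 2 and 3 of CGG with overexpression. The split was 4 higher and 4 lower without CGG array 3, and 3 and 5, 3 and 2, and 9 and 157 without arrays 1, 2 and 3 of CGG with overexpression. TRA2A, WIF1, FABP3 and AKR1B15 passed with each of these arrays left out in turn. TMEM154 did not pass without array 2 of CGG with overexpression, and GDF15, TGM2, ELOVL6 and THRSP did not without CGG array 3 or array 1 or 2 of CGG with overexpression, THRSP also not without CGG array 2. The same 3 arrays and CGG array 1 each ended the calls of MAOA and SAT1, these and CGG array 2 those of ITGB3, ZNF234 and TAFA4, and any 1 of the 6 arrays that of WNT4. With the variance estimated from the 6 arrays alone 3 transcript clusters passed, 2 higher and 1 lower, with TRA2A and FABP3 among them.

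Cholesterol synthesis was the 1 fixed list that kept its call with an estimated correlation (adjusted p = 0.00347), lower with a median of -0.53. Of its 20 genes 1 fell, ACAT2, a cytosolic thiolase (-1.01 ± 0.17), and 12 when adjusted over the list alone, and the call of ACAT2 ended without any 1 of the 6 arrays. Whether TRA2A or a lower amount of the CGG construct gave the falls in this comparison was not tested. The preset correlation called 11 of 27 lists, and 10 lost the call with an estimated correlation. The immediate early list was lower, with 1 of 24 genes called and 6 when adjusted over the list alone (adjusted p = 0.239 with an estimated correlation). That gene, KLF2, a Kruppel-like transcription factor (-1.20 ± 0.20), lost its call without any 1 of the arrays other than array 3 of CGG with overexpression. The SR and Tra2 list was higher, with TRA2A itself the 1 of 23 called, also when adjusted over the list alone (adjusted p = 0.143 with an estimated correlation). Since TRA2A was overexpressed, this call is partly given by the treatment, and the list was not tested without TRA2A. The mitosis list was higher with 0 of 28 genes called, 11 at an unadjusted p under 0.05 and 3 when adjusted over the list alone (adjusted p = 0.143 with an estimated correlation). The metallothioneins were higher with 0 of 10 genes called, 6 at an unadjusted p under 0.05 and 5 when adjusted over the list alone (adjusted p = 0.181 with an estimated correlation).

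The hnRNP and core spliceosome lists, each with adjusted p = 0.409 with an estimated correlation, had no gene past the test in limma (7 and 5 at an unadjusted p under 0.05). The CGG-linked, S phase, histone and ribosomal lists, each with adjusted p = 0.471 with an estimated correlation, had none either (5, 2, 5 and 2 at an unadjusted p under 0.05). The CGG-linked and S phase lists lost the preset call after quantile normalization, and the NF-kB list was then called lower (adjusted p = 0.0494). With an estimated correlation the NF-kB list did not pass on the values as deposited. No stress-response gene passed (0 of 26, 3 at an unadjusted p under 0.05), nor any interferon gene (0 of 30, 4 at an unadjusted p under 0.05). SOD2 was the 1 of 21 NF-kB targets that fell (-1.19 ± 0.17), a call lost without CGG array 2 or 3 or array 2 of CGG with overexpression.

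The comparison of CGG cells with and without TRA2A knockdown asks which genes differ with a loss of TRA2A beside the repeat. CHP1 was 6.95-fold lower (log2 change -2.80 ± 0.19 SE, n = 3 and 3, adjusted p = 5.20e-07) and TRA2A 6.71-fold lower (-2.75 ± 0.19, adjusted p = 5.20e-07). STRADB, a pseudokinase of the LKB1 complex (-2.01 ± 0.23), ARMCX1, an armadillo protein of mitochondria (-1.83 ± 0.28), and SLC15A4, a lysosomal transporter (-1.77 ± 0.20), fell. BABAM1, a subunit of a BRCA1 complex (-1.74 ± 0.26), SZRD1 (-1.71 ± 0.23), MANBAL (-1.65 ± 0.18), BAG2, a co-chaperone (-1.64 ± 0.18), and EHD2, of caveolae (-1.58 ± 0.19), fell too. PTBP2 was 3.44-fold higher (1.78 ± 0.25, adjusted p = 0.00288), and ZNF708 (1.55 ± 0.21) and DCP2 (1.45 ± 0.20) rose. NHLRC3 (1.49 ± 0.28), EGR1 (1.23 ± 0.23), CMKLR2 (1.14 ± 0.22), ZNF680 (1.14 ± 0.22), AGO4, an Argonaute protein (1.12 ± 0.19), CTH, an enzyme of cysteine synthesis (1.12 ± 0.18), and YOD1, a deubiquitinase (1.08 ± 0.21), passed too. CTH lost its call without CGG array 3 or array 2 of CGG with knockdown, AGO4 also without CGG array 2 or array 1 of CGG with knockdown. NHLRC3 lost its call without any array but CGG array 3, EGR1 without any but CGG array 1, CMKLR2 without any but array 2 of CGG with knockdown, and ZNF680 and YOD1 without any 1 of the 6.

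In all, 100 transcript clusters passed, 16 higher and 84 lower, and 4867 had an unadjusted p under 0.05, while a fold of 2 with that p gave 150 higher and 129 lower. The count was 58, 57 and 58 without CGG arrays 1, 2 and 3, 52 and 46 without arrays 1 and 2 of CGG with knockdown, and 53 without the 2 rehybridised arrays. It was 13 with the variance estimated from the 6 arrays alone, with CHP1, TRA2A and DCP2 among those kept and PTBP2, ZNF708, STRADB, ARMCX1 and EHD2 lost. No fixed list kept a call with an estimated correlation (0 of 27, with 1 at an unadjusted p under 0.05; 0 and 3 by fry, a rotation test). The preset correlation called cholesterol synthesis lower, with 0 of 20 genes called in limma, 5 at an unadjusted p under 0.05, and 1 higher and 3 lower when adjusted over the list alone (adjusted p = 0.733 with an estimated correlation). It called the immediate early genes higher, with EGR1 the 1 of 24 called and 2 when adjusted over the list alone (adjusted p = 0.985 with an estimated correlation). No stress-response (0 of 26), interferon (0 of 30) or core spliceosome (0 of 33) gene passed in limma, with 4, 2 and 3 at an unadjusted p under 0.05.

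Knockdown without and with CGG shared 7 higher and 50 lower genes, where independent lists would share 0.180 and 0.353; no array stands in both comparisons. CHP1, TRA2A, STRADB, SLC15A4, SZRD1, MANBAL and BAG2 were lower, and PTBP2 and DCP2 higher, in both. Overexpression without and with CGG shared 2 higher and 2 lower genes, where 0.0569 and 0.0595 would be shared. Across 23836 named genes, which are not independent replicates, the knockdown changes without and with CGG had Pearson r = 0.138 and Spearman rho = 0.0661 (jackknife SE of r 0.0784 over the 12 arrays). The overexpression changes had r = 0.0329 and rho = 0.0723 (SE 0.102). The CGG changes without and with overexpression had r = -0.169 and rho = -0.163 (SE 0.0982), and those without and with knockdown r = -0.101 and rho = -0.108 (SE 0.108). None of these 4 values lay more than 2 SE from 0.

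**Figure D4:**
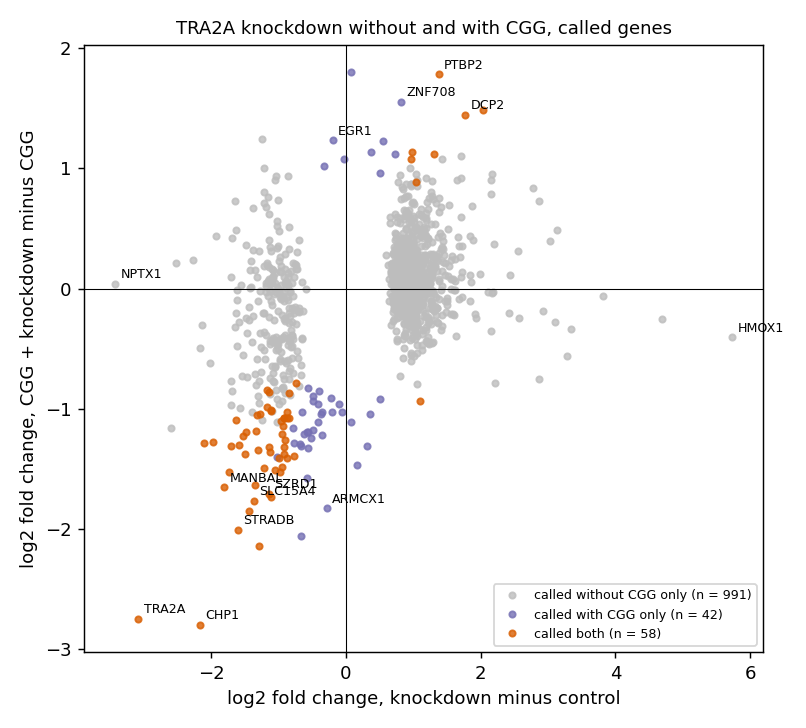
Log2 fold change with TRA2A knockdown in cells without CGG (horizontal axis) and in CGG cells (vertical axis) for each transcript cluster called in either comparison. Those called in both lie mostly at the lower left, with TRA2A and CHP1 below -2 on both axes, while HMOX1 and NPTX1 lie near 0 on the vertical axis.

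The interactions ask whether the CGG change differs between cells with normal and altered TRA2A. With overexpression 167 transcript clusters passed, 33 higher and 134 lower, and with knockdown 119 passed, 31 higher and 88 lower. Without control array 2 the split was 70 higher and 105 lower with overexpression and turned to 148 higher and 109 lower with knockdown. By a fold of 2 with an unadjusted p under 0.05 it turned in both, to 1151 higher and 1047 lower with overexpression and 1239 higher and 889 lower with knockdown. The overexpression arm without CGG also carries the GFP named in its titles. HMOX1 rose 57.0-fold with CGG against controls, while its means without and with CGG were 11.54 and 11.16 in overexpressing and 11.50 and 11.19 in knockdown cells. Its interaction was -6.22 ± 0.40 (adjusted p = 9.93e-08) and -6.14 ± 0.40 (adjusted p = 1.22e-07). SQSTM1 had interactions of -3.82 ± 0.23 and -3.84 ± 0.23, GDF15 -3.60 ± 0.36 and -3.88 ± 0.36, and NPTX1 3.47 ± 0.25 and 3.46 ± 0.25. Of the 167 genes 102, and of the 119 genes 108, were also called in CGG cells against controls in the other direction, a direction favoured by construction, since the interaction subtracts that change on the same arrays. TRA2A, raised by 3.91 on the log2 scale without and by 2.59 with CGG, had an interaction of -1.31 ± 0.27 with overexpression (adjusted p = 0.0472), and the call ended without any 1 of the 12 arrays and after quantile normalization. The overexpression count was 52 without control array 1, 80 and 72 without CGG arrays 2 and 3, and 48 and 97 without overexpression arrays 2 and 3. It was 76, 65 and 277 without arrays 1, 2 and 3 of CGG with overexpression, and 109 without the filter. The knockdown count was 56 and 257 without control arrays 1 and 2, 71 and 57 without CGG arrays 2 and 3, and 49 and 73 without knockdown arrays 1 and 3. It was 60 and 54 without arrays 1 and 2 of CGG with knockdown, and 45 without the 2 rehybridised arrays.

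At the level of exon regions and junctions, each value was taken relative to the value of its gene, so a rise means a rise against the rest of the gene. In CGG cells 1389 of 230888 features changed against controls, 734 higher and 655 lower, 642 of them junctions, in 1048 genes. Junctions of PLAU, urokinase, EMILIN1, an elastic fibre protein, REG1A, a pancreatic secretory protein, CLEC17A, a lectin, and PUSL1, a pseudouridine synthase, rose. Their means were 3.03, 6.96, 6.09, 7.34 and 4.20 in controls, below the filter value of 7.46, and 12.78, 14.72, 14.35, 15.09 and 11.45 in CGG cells, so the size and the order of these rises are uncertain. The gene-level value of PLAU differed by 0.14. Each of these junctions belongs to 162 features, taken up under other observations, that rose by over 2 log2 units in each pair with and without CGG. Of the 162 features, 142 were among the 1389 calls. Inclusion of exons and CGG construct sequence that binds these probes cannot be told apart for these rises. The largest relative falls lay in genes whose gene-level value rose: a region of SQSTM1 (-4.47 ± 0.37), junctions of CSF1 (-4.32 ± 0.68) and ATP6V0B (-4.16 ± 0.86), and a region and a junction of HMOX1 (-3.99 ± 0.37 and -3.98 ± 0.58). Features of genes called at gene level made up 329 of the 1389, and with those genes left out before the adjustment 807 passed. The count was 533 and 3319 without control arrays 1 and 3 and 806 and 613 without CGG arrays 2 and 3. It was 2892 with rehybridisation as a covariate, 2782 without the filter on low features and 176 with the variance of the 6 arrays alone. The ATP6V0B junction lost its call without control array 1 or CGG array 2 or 3, and relative to the median of the exons of the gene the junctions of CSF1 and HMOX1 lost theirs.

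**Figure D5:**
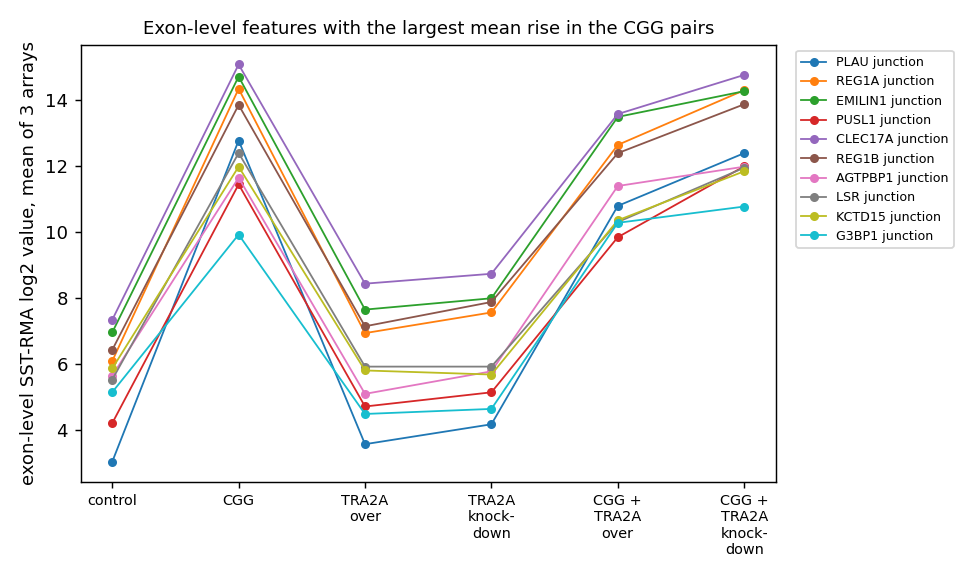
Mean exon-level log2 value of 3 arrays in each group for the 10 features with the largest mean rise over the 3 pairs of groups with and without CGG. The PLAU junction lies at 3.03 in controls and at 12.78, 10.80 and 12.40 in the groups with CGG.

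With TRA2A overexpression 440 relative exon-level values differed from controls, 125 higher and 315 lower. Of 27 tested TRA2A features 14 passed, with changes relative to the gene from -4.59 ± 0.36 to 4.65 ± 0.20. The own means of the lowest of these were 12.89 in controls and 12.21 with overexpression, so its relative fall comes mainly from the gene value, which rose by 3.91, while those of the highest were 10.77 and 19.33. A junction of MVD, an enzyme of sterol synthesis, rose by 4.63 ± 0.39, from a mean of 10.07 ± 0.72 to 15.26 ± 0.06, and rose again in CGG cells with overexpression against CGG cells (4.84 ± 0.39). Its means were 9.27 to 10.07 in the groups without overexpression, and the gene-level value of MVD changed by 0.55 and -0.95 in these comparisons. Whether splicing or TRA2A construct sequence that binds these probes gave the rise was not tested. With knockdown 699 features differed from controls, 234 higher and 465 lower, with 7 of TRA2A. Of these 6 were higher relative to a gene value that fell by 3.08, with own means that differed less, such as 15.50 and 15.18. The largest relative rises with knockdown were a junction of CHP1 (4.18 ± 0.85), whose gene value fell by 2.16, junctions of AKR1B10 (4.12 ± 0.24 and 3.99 ± 0.33) and a region of TRIM16 (3.76 ± 0.29). The largest relative falls were a junction of CSF1 (-4.47 ± 0.68), a region and a junction of HMOX1 (-3.91 ± 0.44 and -3.62 ± 0.58), a junction of GDF15 (-3.82 ± 0.39) and a region of SQSTM1 (-3.55 ± 0.37). A junction of RBM10, a splicing regulator, rose by 3.38 ± 0.26. That junction had a mean of 9.04 ± 0.11 in controls and 11.19 to 12.59 in the 5 other groups. Against CGG cells, 13 features differed with overexpression (6 higher, 7 lower), 6 of them in TRA2A, from -2.61 ± 0.23 to 5.33 ± 0.20. Regions of GLYCAM1 (2.71 ± 0.38) and FBN1 (2.22 ± 0.29) rose, and regions of TREM1 (-2.22 ± 0.30) and PLAT (-1.93 ± 0.21) fell. With knockdown 18 features differed from CGG cells (17 higher, 1 lower), 6 of them regions of TRA2A that were higher relative to its lower gene value. A junction of CHP1 rose by 3.13 ± 0.21, with own means of 16.78 ± 0.18 and 17.12 ± 0.08. The 1 fall was a region of PTBP2 (-1.83 ± 0.27), whose gene value rose by 1.78. Features of genes called at gene level made up 196, 345, 6 and 17 of the calls in these 4 comparisons. With such genes left out, 105, 137, 3 and 0 features passed in limma (26690, 24619, 20310 and 10885 at an unadjusted p under 0.05). The counts without single arrays were 109 and 2715 (control arrays 1 and 3) and 283, 113 and 99 (overexpression arrays 1, 2 and 3) for overexpression. For knockdown they were 249 and 2182 (control arrays 1 and 3) and 154 and 449 (knockdown arrays 1 and 2). In CGG cells they were 44 and 8 (CGG arrays 1 and 3) and 8 (array 2 of CGG with overexpression) for overexpression, and 11 and 9 (CGG arrays 2 and 3) and 10 and 8 (arrays 1 and 2 of CGG with knockdown) for knockdown.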

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

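The 2 interactions were planned, while the tests of chance values in the shared controls, of a single unusual control array and of a state common to all treated cells were chosen after the shared calls were seen. The interactions tested whether the CGG change differs with TRA2A level, and 167 genes passed with overexpression and 119 with knockdown. With overexpression the largest positive interactions were NPTX1 at 3.47, MALT1 at 2.49, ALPK2 at 2.35, WWC1 at 2.33, ANKRD1 at 2.27, BMP4 at 2.0, TAFA4 at 1.81, MTMR10 at 1.76, DCDC2 at 1.75 and EGR1 at 1.74 (log2). The largest negative ones were HMOX1 at -6.22, AKR1B15 at -4.84, the 5S RNA pseudogenes RNA5SP389, RNA5SP199, RNA5SP298 and RNA5SP71 at -4.41, -4.02, -3.18 and -3.06, SQSTM1 at -3.82, GDF15 at -3.60, FABP3 at -3.56 and AKR1B10 at -3.30. TRA2A itself had -1.31, a call lost when any 1 of the 12 arrays was left out. With knockdown the largest positive ones were NPTX1 at 3.46, ANKRD1 at 2.74, ALPK2 at 2.50, MALT1 at 2.37, MTMR10 at 1.85, WWC1 at 1.84, EEIG2 at 1.80, TAFA4 at 1.61, TM4SF1 at 1.61 and CYP24A1 at 1.58. The largest negative ones were HMOX1 at -6.14, AKR1B15 at -4.95, GDF15 at -3.88, SQSTM1 at -3.84, AKR1B10 at -3.68, FABP3 at -3.62, GPNMB at -3.11, AKR1B10P1 at -3.00, EPHX1 at -2.81 and CSF1 at -2.65. Of 100 splits of the 12 arrays, the real one included, 1 gave as many calls for the overexpression interaction (167, highest other 90). For the knockdown interaction 2 did (119, highest other 240). Each split exchanged arrays with and without CGG inside each TRA2A background, so it took away the CGG difference together with the interaction. The splits therefore do not exclude chance for an interaction. Why another split gave 240 calls for the knockdown interaction was not tested.

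The genes called the same way against control in CGG, overexpressing and knockdown cells, 187 in all (147 higher, 40 lower), made up 73 of the 167 and 74 of the 119 interaction genes. The mean covariance of the 3 sets of fold changes was 0.0819, against at most 0.0346 in simulated data without a change. The simulated values hardly spread (mean 0.0336), while real arrays can vary together across genes, which would widen that range. The covariance therefore does not decide on chance values of the shared control arrays. A single unusual control array is argued against by picking the genes without 1 control array. The array left out lay beyond all 15 other arrays on the side of the controls in 94.5% (69 of 73), 67.2% (135 of 201) and 66.7% (216 of 324) of these genes for control arrays 1, 2 and 3. Many of the 15 arrays also served to pick the genes, which favours this outcome. The median change of the 3 groups used, against the array left out, was 1.48, 0.888 and 0.668, so the control arrays differed in how far they lay apart. A state common to all treated cells, such as transfection or separate handling of the control arrays, is in line with the 2 groups not used to pick the genes, whose median change against the control array not used to pick them was 0.970, 0.817 and 0.874 of that in the 3 groups used for control arrays 1, 2 and 3, while 14 of the 187 genes (7.49%) differed among the 5 treated groups, a larger share than the 445 of 67854 tested. The labels do not say whether the controls were transfected, so transfection, handling of the controls and an effect of each treatment on the same genes cannot be told apart. If the common state is the source, the interactions of these genes may reflect the place of the controls rather than a dependence of the CGG response on TRA2A, and neither the interactions of the other genes nor the GFP named for overexpression without CGG were weighed.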

How the results depend on the processing

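The runs without the 2 rehybridised arrays, with only features of genes not called at gene level, without the rising CGG features and with the other treated groups as reference were chosen after seeing the data; the rest were planned, and unless stated the cause was not tested. The counts are given in the order CGG, overexpression, knockdown (against control), overexpression in CGG, knockdown in CGG, and the overexpression and knockdown interactions. Main counts were 454, 846, 1049, 26, 100, 167 and 119 at gene level and 1389, 440, 699, 13 and 18 at exon level. Counts moved beyond 1.5 times as follows. Without a filter: overexpression 563, overexpression in CGG 16, its interaction 109; at exon level 2782, 1044, 1850 and 27 (more features were tested). Stricter filter (fewer genes tested): 810, 1891, 1669, and interactions 326 and 225. Variance from only the arrays compared (fewer residual degrees of freedom): 55, 33, 135, 3, 13, 53 and 35; at exon level 176, 33, 14, 2 and 0, the last with 11286 at an unadjusted p under 0.05 in limma. Trended and robust variance: CGG 783, overexpression 1714, in CGG 66 and 156, interactions 297 and 241. Rehybridisation as a covariate: overexpression in CGG 15, knockdown interaction 49; at exon level CGG 2892, knockdown 2058, overexpression in CGG 209. Without the 2 rehybridised arrays: knockdown 526, in CGG 12 and 53, knockdown interaction 45; at exon level overexpression in CGG 71. Fold of 2 with an unadjusted p: in CGG 302 and 279, interactions 2198 and 2128. Only features of genes not called at gene level: 807, 105, 137, 3 and 0, the last with 10885 at an unadjusted p under 0.05. The mean of the 2 other treated groups as reference: 9, 126 and 238, and there AKR1B15 (-1.33), AKR1B10 (-1.13), GDF15 (-2.01), CDKN1A (-1.14) and INSIG1 (-1.05), all higher with overexpression against control, were reversed, since these genes were higher still in the groups then used as reference. Leaving out each array in turn gave 179 to 703, 188 to 1524, 481 to 1319, 5 to 166, 46 to 80, 48 to 277 and 49 to 257 at gene level, and 533 to 3319, 99 to 2715, 154 to 2182, 8 to 44 and 8 to 18 at exon level. Of the lists called with the preset correlation (11, 14, 14, 11 and 2), 4, 3, 5, 1 and 0 passed with an estimated correlation (7, 8, 9, 5 and 1 at an unadjusted p under 0.05), and by fry 7 for CGG, 5 for overexpression in CGG and 0 for knockdown in CGG (3 at an unadjusted p under 0.05). Quantile normalization and the replicate number as a block kept every gene-level count within 1.5 times; the latter gave 433, 816, 1016, 20, 76, 165 and 88, and 45 same-numbered pairs of arrays correlated at -0.121 to 0.158, 3 over 0.1, so the numbers gave no pairing. Named genes kept their side of the threshold 412 times with quantile normalization (17 lost, 3 gained), 304 with only the arrays compared (128 lost) and 2495 over the leave-one-out fits (360 lost, 13 gained), none reversed in these. The 4 correlations kept their signs or stayed within their errors in each alternative, with a range of -0.0264 to 0.0927 for overexpression and -0.147 to -0.0143 for CGG with and without knockdown when 1 array was left out. Transcript clusters below the median level, near the array background, were not tested in the main comparisons, and changes of 1 log2 unit were recovered in 43 of 100 simulated genes at gene level and 10 of 100 at exon level.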

Other observations

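The lists of NRF2 targets and lysosomal genes, the comparison among treated groups, and the tests of construct sequence and of siRNA off-target action were chosen after the results were seen, while those of exon inclusion, of the TRA2A level and of other splits were planned. Of 27 measured targets of NRF2, the regulator of the antioxidant response, 17 were higher in CGG, 16 in overexpressing and 19 in knockdown cells against control, with medians of 1.18, 1.01 and 1.29. NQO1, a quinone reductase, rose by 2.10 and EPHX1, an epoxide hydrolase, by 2.29 in CGG cells. Of 31 lysosomal genes 13, 10 and 20 were higher (medians 0.79, 0.67 and 0.84), with CTSD, the protease cathepsin D, at 2.14 and ATP6V0D1, of the vacuolar proton pump, at 1.36 in CGG cells. Both lists were put together after their members among the largest rises, such as HMOX1, GPNMB and ATP6V0B, had been seen, so neither direction is independent evidence and no test against other genes is given.

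Among treated groups, each against the mean of the others compared with control, overexpressing cells were higher in TRA2A (5.47) and SPOCK1, an extracellular proteoglycan (1.26), and lower in the cytokine IL6 (-1.83), CRYAB (-1.79) and ITGB3 (-1.73), all called the same way against control. They were also higher in WIF1 (1.97) and lower in FABP3 (-2.26), which had changes of 0.58 and 0.87 against control and did not pass there. BMP4 was higher than in the other treated groups (1.12) but fell against control (-1.15), and GDF15 was lower than in these (-2.01) but rose against control (1.81). Knockdown cells were lower in TRA2A (-5.00), CHP1 (-2.60), BAG2 (-1.93), ZCCHC9 (-1.82) and SZRD1 (-1.75), and higher in NHLRC3 (1.63), DCP2 (1.48) and INSIG1 (1.29), all called the same way against control. CGG cells had 9 calls, 8 higher and 1 lower, among them FABP3, with a change of 3.37 against control, and CHP1 at 1.32, with 0.45 against control (adjusted p = 0.324) and a fall of 2.16 in the knockdown cells of the reference.

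A total of 162 exon-level features (95 junctions) in 150 genes rose by over 2 log2 units in each of the 3 pairs of groups with and without CGG, 0 fell, and their genes changed by a median of 0.15 against 4.05 for the features. Inclusion of exons of the host genes was tested by whether a feature lay above every other feature of its gene in CGG arrays, which 28.4% did. In control arrays 6.17% of them did, and of 2000 drawn tested features 8.7% did in CGG arrays. The features were picked for their rise, which favours a high share, and levels of different probes are not comparable. The share therefore does not bear on inclusion either way. Sequence of the CGG construct that binds these probes may be the source, as 86.4% of the features (140 of 162) were lower in CGG with overexpression than in CGG (median -0.89, all features 0.04), which a lower amount of 1 construct would give. A general change of splicing with overexpression would also shift many features, the construct sequence is not in the labels, and 0 of 64 FMR1 features rose by this measure (largest mean rise 0.31), so construct and inclusion cannot be told apart.

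Knockdown called 56 genes besides TRA2A the same way without and with CGG, 49 lower and 7 higher. If the TRA2A level were the cause, overexpression might move them the other way, and 60.7% (34 of 56) did in CGG cells and 39 of 56 without CGG. The genes were picked against the same CGG and control arrays that are the reference here, which lowers these shares by construction. In CGG cells the median change in the knockdown direction was -0.09 with overexpression against 1.29 with knockdown. None of the 56 was called the other way there in limma, where 26 genes passed and 6112 had an unadjusted p under 0.05. The siRNA acting on transcripts other than TRA2A is consistent with the 49 genes that fell, among them CHP1, STRADB, SLC15A4 and IGF2BP2. TRA2A level and off-target action cannot be told apart, because the labels give neither the sequence nor the number of siRNAs, and overexpression need not mirror a loss.

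Other splits of the 6 arrays of a pairwise comparison number 10 with the real one, too few for a share under 0.05. In the order CGG, overexpression and knockdown against control, then overexpression and knockdown in CGG cells, the real gene counts were 454, 846, 1049, 26 and 100, and the highest of the other splits 3, 2, 0, 1 and 1, with 1 split, the real one, as large in each. At the exon level the real counts were 1389, 440, 699, 13 and 18 and the highest others 1, 1, 0, 0 and 0, again with 1 split as large. For the gene lists the real counts were 11, 14, 14, 11 and 2 and the highest others 19, 18, 17, 4 and 6, with 2, 4, 2, 1 and 5 splits as large, the real one included. Each other split sets 2 arrays of one group with 1 of the other and so keeps part of the real difference, and why some gave more list calls than the real one was not tested.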
